A study of Mus musculus with 63 samples.

How the data were processed

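Bulk RNA sequencing of ovaries and pituitaries of female C57BL/6 mice was analysed, with 63 libraries in all. Per the labels, total RNA was extracted with chloroform and libraries were made with the NEBNext Ultra II RNA kit. The aligner, the counting program and the annotation are not given in the sources used here. For each tissue the authors deposited a table of raw read counts per gene and, beside them, FPKM values, which are counts per kilobase of gene and scaled by the library total. The deposited FPKM values were checked against the counts: 100% of 420558 values in the ovary table and of 426322 in the pituitary table lay within 1% of the count divided by the library total and by 1 fixed length per gene. FPKM values were used in no comparison. The gene positions in the tables are those of mouse genome build GRCm38. Each table holds 34745 genes, and 126 gene names that occur more than once were kept apart by their identifiers. Every column of sample values was assigned to a labelled sample. None of 93 pairs of libraries within a group held the same counts, and the closest pair had a chi-square of 8.88 per degree of freedom, above counting noise.

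Samples were grouped by tissue, age (2 or 6 months), duration (8 or 12 weeks) and treatment (control or CUMS), with 4 libraries per group except the 6M-12W control ovaries with 3. The tissues were fitted apart, each with its 8 groups in 1 model. Genes were kept with edgeR's filterByExpr, which left 17766 in ovary and 17001 in pituitary. Libraries were scaled with TMM factors. The test was edgeR 4.0.16's quasi-likelihood F test in R 4.3.3 (biological coefficient of variation 0.207 in ovary and 0.158 in pituitary), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Folds are on the log2 scale, stressed over control, and the SE of a fold is its size divided by the square root of F. CPM means are given with the SD between libraries. Per tissue 11 contrasts were made: stress against control in each of the 4 sets and as the mean of the 4 sets, the difference of the stress effect between ages at each duration and between durations at each age, the 6M-12W minus the 2M-8W stress effect, and 6-month against 2-month controls. For each tissue 31 gene lists (cell-type markers, hormones and receptors, and pathways) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated one, and with fry. The comparisons, the gene lists, the rule for named genes and the first group of alternatives below were fixed before the data were examined.

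Genes were named by rule. In each stress comparison these are the core genes of the tissue (21 in ovary, 18 in pituitary, of which 17 were tested), the 6 highest and 6 lowest folds past the threshold with a mean log2 CPM of at least 1, predicted genes and pseudogenes left out, and the 4 members with the smallest p in each list that was called or had 3 members past the threshold. In the other contrasts they are the 5 highest and 5 lowest folds by the same limits and the core genes past the threshold. Where none passed, the 5 with the smallest p.

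The pipeline was tested on simulated data with the same depths and dispersions. Of genes simulated with a change of 2 times and of 4 times in 1 set, it recovered 87% and 96% in ovary and 91% and 99% in pituitary, and false calls made up 4.90% and 4.53% of the calls. With DESeq2 1.42.0 these shares were 14.9% and 8.94%. Genes were simulated independently, with no library made to stand apart, and those picked to change had a mean of at least 2 CPM. Recovery and false calls in the real data may therefore differ. Alternatives were DESeq2's Wald test, RLE size factors, no filter on low counts, a fit of each comparison's own groups only, the replicate number as a block, each library left out in turn, and the estimated inter-gene correlation. Alternatives chosen after seeing the data left out the 2M-8W stressed ovaries 1 and 3, left out the 6M-12W control pituitaries 3 and 4, left out genes at least 100 times more abundant in the other tissue, or took age in controls from the 8W or the 12W sets alone. No library was left out of the values reported. A few genes that the rule names are not reported here.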

Results

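RNA was sequenced from ovaries and pituitaries of female mice that had gone through chronic unpredictable mild stress (CUMS), a schedule of varied mild stressors, and of unstressed controls. The titles give an age of 2 or 6 months and a duration of 8 or 12 weeks, which makes 4 sets per tissue, called here 2M-8W, 2M-12W, 6M-8W and 6M-12W. Each set has 4 stressed and 4 control libraries, except 6M-12W ovary with 3 controls. Total counts were 12536371 to 28777668 in the 31 ovary libraries and 13514270 to 24924584 in the 32 pituitary libraries. The title of the series asks whether young and adult females respond differently along the hypothalamic-pituitary-ovarian axis. Whether age was counted at the start or the end of stress, the estrous stage, the hour of collection and the sequencing batch are not given in the sources used here. For comparisons between sets a batch that follows the sets and the set cannot be told apart. Whether control and stressed samples of a set were handled or sequenced together is not given either. Levels of transcripts of the other tissue, given below, differed between them in some sets.

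Stress was followed by more changed genes in the ovary than in the pituitary in 3 of the 4 sets. In the ovary 1113 genes passed the test in 2M-8W (703 higher in stressed animals, 410 lower), 1197 in 2M-12W (459 higher, 738 lower), 199 in 6M-8W (99 higher, 100 lower) and 2032 in 6M-12W (920 higher, 1112 lower). In the pituitary the counts were 72 (41 higher, 31 lower), 99 (66 and 33), 799 (391 and 408) and 47 (17 and 30). As the mean of the 4 sets, each against its own controls, 3615 ovary genes (1574 higher, 2041 lower) and 1095 pituitary genes (522 higher, 573 lower) passed. These 2 mean counts stayed within 1.5 times of their values with any single library left out (2748 to 3997 and 918 to 1253), whereas the counts of single sets did not. The ranking of the tissues does not hold throughout. In fits of own groups only, 2M-8W had 2 ovary and 18 pituitary genes, and 2M-12W had 0 ovary genes in edgeR (3465 at an unadjusted p under 0.05; 1745 with DESeq2 in the fit of all groups) and 91 pituitary genes. Without control ovary 4 the 2M-8W ovary count is 36 (9 higher, 27 lower), and without control ovary 2 it is 45 (10 higher, 35 lower), below the 72 of the pituitary. With the replicate number as a block it is 125 (58 higher, 67 lower), so the surplus of higher genes in this set does not hold either.

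**Figure D1:**
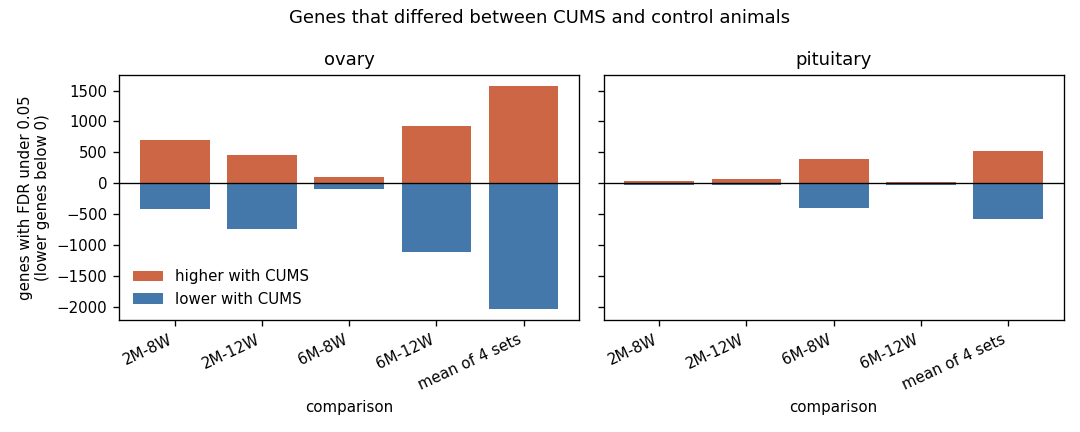
Number of genes past an adjusted p of 0.05 (y axis) in each stress comparison (x axis), higher and lower in stressed animals shown apart, for ovary and pituitary. The ovary counts range from 199 in 6M-8W to 2032 in 6M-12W, and the pituitary counts from 47 in 6M-12W to 799 in 6M-8W.

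In the stressed pituitary transcripts listed for the corticotrope, the cell that drives the adrenal, rose together. Pomc, which encodes the precursor of ACTH, was higher by 0.97 ± 0.12 (log2 fold ± SE, mean of the 4 sets, adjusted p = 2.19e-06) and lay above its control mean in 16 of 16 stressed pituitaries. The receptors through which the hypothalamus drives this cell rose as well, Crhr1 by 0.50 ± 0.07 (adjusted p = 2.18e-05, 16 of 16) and Avpr1b by 0.46 ± 0.10 (adjusted p = 0.00247, 15 of 16). Of the 5 corticotrope genes 4 rose, with a median of 0.50, and the list kept its call with an estimated correlation (adjusted p = 0.00334). Pomc is in the melanotrope list too, so its rise cannot be assigned to the corticotrope alone. Glucocorticoid-responsive transcripts rose too: 9 of 24 passed (14 rose and 1 fell adjusted over the list alone; adjusted p = 0.00135 with an estimated correlation). Among them were the receptor co-chaperone Fkbp5 (0.61 ± 0.07, adjusted p = 4.58e-07, 16 of 16) and Tsc22d3, which encodes GILZ (0.35 ± 0.07, adjusted p = 0.00151, 13 of 16). Tshb, the thyrotropin subunit, rose by 0.33 ± 0.09 (adjusted p = 0.0183, 14 of 16). Of the 24 cell cycle genes 10 fell (16 adjusted over the list alone; median -0.54; adjusted p = 0.0366 with an estimated correlation). Leading them were Mki67 (-1.25 ± 0.19, adjusted p = 7.09e-05, 16 of 16) and Top2a (-1.22 ± 0.22, adjusted p = 0.000695, 15 of 16). Cxcl10, an interferon-induced chemokine, fell by 1.14 ± 0.29 (adjusted p = 0.0153, 15 of 16). Each gene named in this paragraph passed under all 38 alternatives run on the mean. Pomc (ENSMUSG00000020660) lies on chromosome 12 at 3954951 to 3960618 of GRCm38, and Fkbp5 (ENSMUSG00000024222) on chromosome 17 at 28399095 to 28517524.

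**Figure D2:**
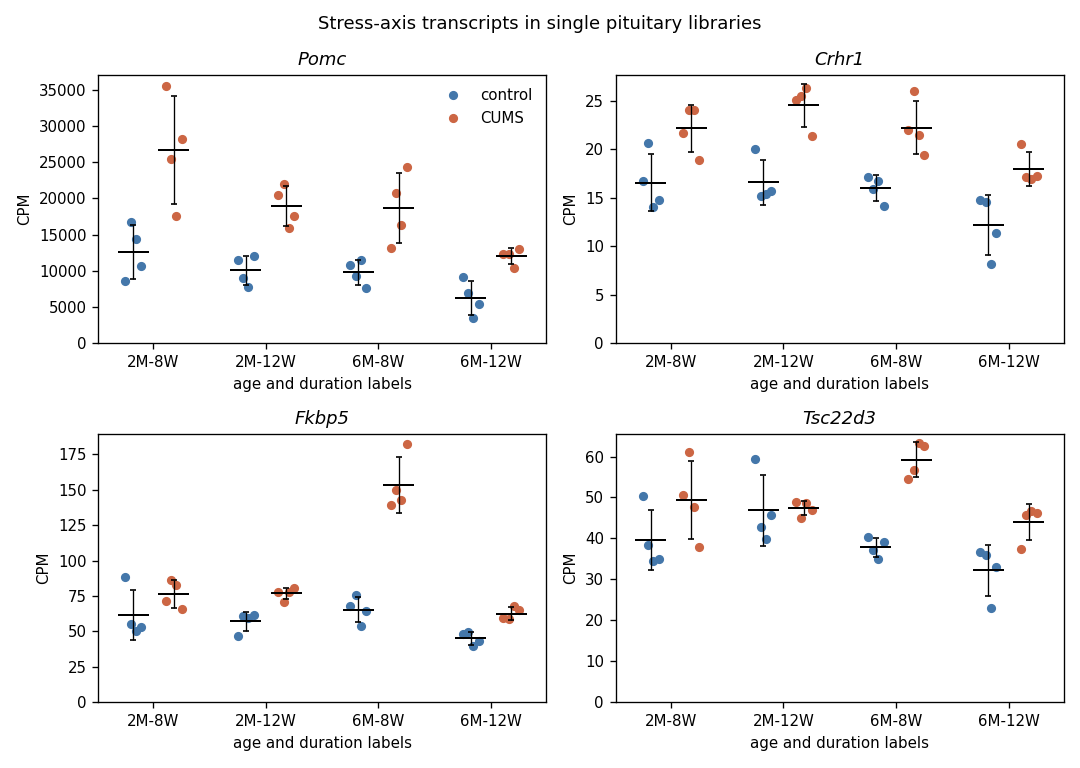
CPM per library (y axis) of Pomc, Crhr1, Fkbp5 and Tsc22d3 in control and stressed pituitaries of each set (x axis), with points for libraries and bars for the mean ± SD. In every set the 4 stressed pituitaries lie above all 4 controls for Pomc.

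The gonadotropin and lactotrope transcripts did not pass the test. Lhb, Fshb and Cga, the gonadotropin subunits, the GnRH receptor Gnrhr, Prl and Gh passed neither in a single set nor in the mean of the 4 sets. For example, Lhb was at 287 ± 38.9 CPM in 2M-8W controls and 256 ± 23.8 in stressed pituitaries (-0.16 ± 0.16, adjusted p = 0.905). Fshb had the largest folds of these genes, with 254 ± 81.8 and 109 ± 51.4 CPM in 2M-12W (-1.21 ± 0.63, adjusted p = 0.528, lower in 4 of 4). Of the 8 gonadotrope genes 2 rose in the mean of the 4 sets (median 0.13; adjusted p = 0.357 with an estimated correlation).

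Several clock genes changed in every pituitary set and in the same direction, Arntl and Npas2 downward and Dbp, Ciart, Per2, Per3, Tef, Nr1d2 and Bhlhe41 upward. Nr1d1 did not: it rose in 3 sets and had a fold of -0.14 in 6M-12W (adjusted p = 0.755). In the mean of the 4 sets Arntl, which encodes BMAL1, fell by 1.17 ± 0.06 (adjusted p = 3.32e-14), Npas2 fell by 2.18 ± 0.12 (adjusted p = 1.90e-13). Dbp rose by 1.87 ± 0.10 (adjusted p = 1.52e-13), Ciart by 1.99 ± 0.13 (adjusted p = 6.57e-12) and Per2 by 1.27 ± 0.09 (adjusted p = 7.47e-12). Of the 18 clock genes 10 rose and 3 fell (adjusted p = 0.0274 with an estimated correlation). The ovary showed a smaller change of the same kind, with 8 of 18 up and 3 down in the mean of the 4 sets (adjusted p = 0.119 with an estimated correlation). A clock measure was the mean log2 CPM of output genes minus that of the activators Arntl and Npas2. The output genes were Dbp, Tef, Per2, Per3, Nr1d1, Nr1d2, Ciart and Bhlhe41. This measure was higher in stressed than in control pituitaries by 3.43 ± 0.18 (SE) in 2M-8W, 3.12 in 2M-12W, 2.78 in 6M-8W and 2.35 in 6M-12W. In ovaries it was higher by 1.36 ± 0.29, 1.45, 1.33 and 0.63 (± 0.31 in the last). All 4 stressed libraries lay above all controls in each of the 8 comparisons. All genes of the measure but Nr1d1 were called in all 4 pituitary sets. In the pituitary this separation therefore largely follows from the choice of genes and is no separate support. Controls differed between sets as well: in 6M-12W they were at 2.38 in pituitary and 2.72 in ovary, against 0.52 to 0.79 and 0.77 to 1.25 in the other sets, and the ovary control mean there lay above the stressed means of the other sets (2.10 to 2.61). Across the 18 genes the log2 folds of ovary and pituitary correlated with Pearson's r of 0.662, 0.720, 0.756 and 0.735 in the sets in that order (Spearman's rho 0.538, 0.620, 0.600 and 0.721) and 0.773 in the mean of the 4 sets (rho 0.676). Genes are not independent replicates. Permutation p values (100000 resamples, either direction) were 0.0029, 0.00072, 0.00031, 0.00048 and 0.00021, and after adjustment over these 5 relations 0.0029, 0.0009, 0.000775, 0.0008 and 0.000775. Since the hour of collection is unknown, whether both arms were taken at the same hour is unknown too.

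**Figure D3:**
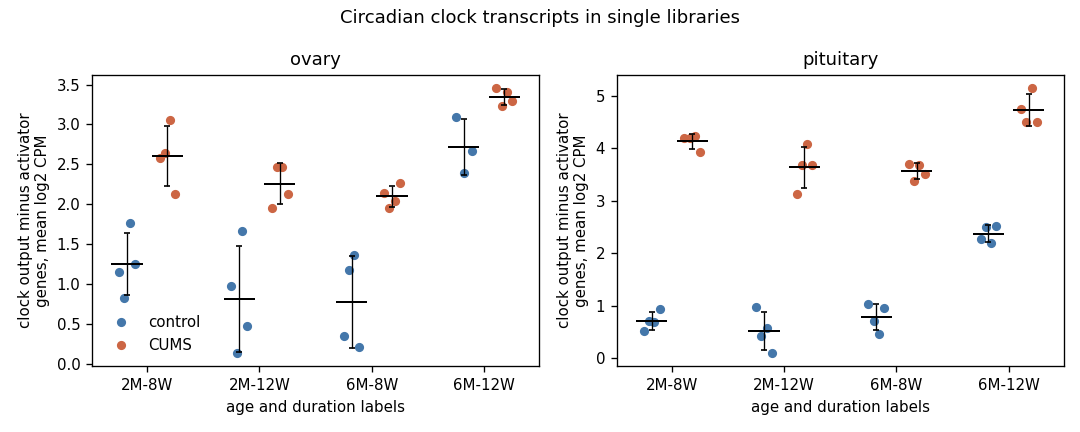
Mean log2 CPM of clock output genes minus that of clock activator genes (y axis) per library, in control and stressed animals of each set (x axis), for ovary and pituitary, with bars for the mean ± SD. All stressed libraries lie above all controls of their set in both tissues. The genes used, but for Nr1d1, were called in every pituitary set.

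In 2M-8W pituitaries of stressed mice Pomc was higher and clock genes differed. Pomc went from 12610 ± 3665 to 26654 ± 7393 CPM (1.08 ± 0.24, adjusted p = 0.0302, higher in 4 of 4; past the threshold in 6 of 14 alternatives). The other melanotrope genes tested, Pcsk2 (0.32), Oacyl (0.25) and Pax7 (0.19), had folds above 0 without passing. Of the 18 clock genes 8 rose and 2 fell (10 and 6 adjusted over the list alone; adjusted p = 0.0760 with an estimated correlation). Dbp went from 29.6 ± 7.79 to 151 ± 25.1 CPM (2.35 ± 0.21, adjusted p = 4.22e-08, 4 of 4) and Arntl from 50.7 to 18.9 (-1.42 ± 0.12, adjusted p = 1.50e-08, 4 of 4). Beyond the clock, the histamine receptor Hrh3 (1.58), Tsku (1.36), the deiodinase Dio1 (1.35) and Cyp2a5 (2.60 ± 0.47, adjusted p = 0.00333) rose. The desaturase Scd3 fell by 1.32 ± 0.21 (adjusted p = 0.000428), as did Tmem132d (-0.98) and Fstl4 (-0.97), each in 4 of 4 stressed pituitaries. Cyp2f2, a marker of folliculostellate cells, rose by 0.55. Pcdhga2 (-3.94) shares exons with other protocadherins, so that its fold is uncertain. The count of 72 fell to 41 without stressed pituitary 2 and to 45 without control 4, and to 18 in a fit of these groups alone.

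In 2M-12W pituitaries clock genes were among those with the smallest adjusted p. Nr1d1, the repressor REV-ERB alpha, rose from 41.7 ± 7.59 to 187 ± 21.7 CPM (2.16 ± 0.14, adjusted p = 3.04e-11) and Dbp from 19.9 ± 4.87 to 119.5 ± 15.9 (2.58 ± 0.21, adjusted p = 4.27e-09), each in 4 of 4. In all, 8 clock genes rose while 3 fell (adjusted p = 0.0828 with an estimated correlation). The cadherin Cdh13 (1.49 ± 0.27), the G protein Rasd2 (1.34 ± 0.19), Cyp2a5 (1.97 ± 0.46) and the metallothionein Mt1 (0.52) rose. Sez6l (-1.28 ± 0.24), the histone gene Hist1h3d (-1.28 ± 0.26) and Smco2 (-0.92) fell, with adjusted p of 0.000129 to 0.0431. Pomc was at 10061 ± 2024 and 18996 ± 2753 CPM (0.92 ± 0.24, adjusted p = 0.0720), above all controls in 4 of 4, without passing. 4 of 5 corticotrope genes rose and 1 fell adjusted over the list alone (adjusted p = 0.0828 with an estimated correlation). The count of 99 ranged from 34 without stressed pituitary 3 to 178 without control 1.

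The 6M-8W pituitaries had the most changed genes of the pituitary sets, 799, and a glucocorticoid signature. Fkbp5 rose from 65.5 ± 9.09 to 153.5 ± 19.9 CPM (1.23 ± 0.14, adjusted p = 2.03e-06) and Tsc22d3 from 37.9 ± 2.35 to 59.3 ± 4.32 (0.65 ± 0.14, adjusted p = 0.00512), each in 4 of 4 and under all 14 alternatives. In all, 11 of 24 glucocorticoid-responsive genes rose (14 adjusted over the list alone; median 0.51), among them Map3k6 (1.46 ± 0.20), Mt2 (0.92 ± 0.13) and Hif3a (0.96 ± 0.14), and the list kept its call with an estimated correlation (adjusted p = 0.000269). The corticotrope factor Tbx19 (0.82 ± 0.14, adjusted p = 0.000335) and Pomc (9807 ± 1749 to 18662 ± 4871 CPM, 0.93 ± 0.24, adjusted p = 0.0197) rose, 2 of 5 corticotrope genes in all (adjusted p = 0.0727 with an estimated correlation). The nicotinic receptor subunit Chrna6 went from 21.4 ± 6.23 to 129 ± 18.9 CPM (2.59 ± 0.45, adjusted p = 0.000561). The exocytosis factor Doc2b went from 6.93 ± 1.60 to 39.95 ± 1.87 (adjusted p = 3.80e-08) and Nwd2 from 1.82 ± 0.42 to 8.11 ± 4.28 (adjusted p = 0.000105), each in 4 of 4. Tgm6, a transglutaminase gene, fell by 1.62 ± 0.43. Of 20 genes of the unfolded protein response 3 rose, Herpud1 (0.64), Dnajb9 (0.77) and Ddit3 (0.39) (adjusted p = 0.369 with an estimated correlation). Of 12 heat shock genes 1 rose, Hspb1 (1.18; 10 adjusted over the list alone; adjusted p = 0.711 with an estimated correlation). The clock list had 9 up and 2 down (adjusted p = 0.119 with an estimated correlation). The secretory proteins Dmbt1 (-5.78) and Ltf (-5.39) rest on control 3, without which their folds are 1.87 and -0.30. The count of 799 fell to 436 without stressed pituitary 4, to 455 without stressed pituitary 3 and to 511 without control 4. The ovarian enzyme transcript Hsd3b1 was at 0 CPM in controls of this set and at 3.68 ± 0.31 in stressed pituitaries. If these arms were sequenced apart, batch and stress cannot be told apart in the results of this set.

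In 6M-12W pituitaries 47 genes passed, 9 of them in the clock list. Per2 rose from 35.4 ± 3.56 to 87.4 ± 5.49 CPM (1.30 ± 0.17, adjusted p = 6.88e-05), Tef by 1.14 ± 0.14 and Ciart by 1.66 ± 0.26. Arntl fell by 1.01 ± 0.12 (adjusted p = 2.70e-05), each in 4 of 4. The clock list had 7 up and 2 down (adjusted p = 0.176 with an estimated correlation). The proliferation marker Mki67 fell from 6.58 ± 3.82 to 1.81 ± 0.63 CPM (-1.85 ± 0.39, adjusted p = 0.0244, 4 of 4), 1 of 24 cell cycle genes (8 adjusted over the list alone; median -0.77; adjusted p = 0.143 with an estimated correlation). The leukocyte adaptor Lcp2 (-1.29 ± 0.23) and Fcer1g (-0.76 ± 0.17), an Fc receptor subunit of macrophages, fell, and 9 of 16 macrophage genes fell and 1 rose adjusted over the list alone (adjusted p = 0.0625 with an estimated correlation). Folds were below 0 for 8 of 10 endothelium genes (median -0.23; adjusted p = 0.292 with an estimated correlation) and 19 of 20 matrix genes (median -0.28; adjusted p = 0.143 with an estimated correlation), none past the threshold alone. All 5 corticotrope genes had folds above 0 (median 0.55; 4 adjusted over the list alone), and this list kept its call with an estimated correlation (adjusted p = 0.0304). Pomc, at 6243 ± 2361 and 12033 ± 1104 CPM, did not pass alone (0.95 ± 0.24, adjusted p = 0.0897, 4 of 4). Also higher were Cpne7 (1.24) and the calcium pump Atp2a1 (1.04), and lower Ahdc1 (-1.21) and Scd3 (-1.19). Both arms of this set differed in RNA composition from most other pituitaries, with 4.19 to 10.02% of counts from mitochondrial genes in controls and 4.34 to 6.44% in stressed animals. The count of 47 became 22 without stressed pituitary 4, 31 without control 3 and 92 without control 1. Without controls 3 and 4, a choice made after seeing the data, 40 genes passed, 16 of them among the 47.

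In ovaries of stressed mice most ovulation genes and part of the luteal genes were lower, and theca genes and part of the follicle genes were higher. In the mean of the 4 sets 12 of 18 genes of the LH surge and ovulation fell (median -1.34; 13 fell and 1 rose adjusted over the list alone; adjusted p = 0.119 with an estimated correlation). So did 17 of 20 immediate early genes (median -0.65; 19 adjusted over the list alone; adjusted p = 0.119 with an estimated correlation) and 6 of 12 luteal genes (median -0.35; 6 adjusted over the list alone; adjusted p = 0.409 with an estimated correlation). Among the core genes the LH receptor Lhcgr fell by 0.66 ± 0.19 (adjusted p = 0.0137, lower in 13 of 16 stressed ovaries). The prolactin receptor Prlr fell by 0.62 ± 0.14 (adjusted p = 0.00191, 13 of 16) and the side-chain cleavage enzyme Cyp11a1 fell by 0.41 ± 0.12 (adjusted p = 0.0127, 13 of 16). Theca genes and some follicle genes rose. The androgen-forming enzyme Cyp17a1 did so by 1.21 ± 0.36 (adjusted p = 0.0172, 13 of 16), the estrogen receptor Esr2 by 0.55 ± 0.12 (adjusted p = 0.00243, 14 of 16), the inhibin subunit Inha by 0.46 ± 0.12 (adjusted p = 0.00569, 14 of 16). So did 7 of 7 theca genes (median 0.42; adjusted p = 0.119 with an estimated correlation) and 6 of 17 granulosa genes (median 0.33; 11 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation). Of the oocyte genes 5 of 25 rose, with all 25 folds above 0 (median 0.33; 9 adjusted over the list alone; adjusted p = 0.409 with an estimated correlation). Zp3, an egg coat protein, rose by 0.36 ± 0.12 (adjusted p = 0.0364, 13 of 16) and passed in 25 of 37 alternatives. The other core genes named here passed in all 37. The luteal and follicle genes did not go one way in all sets. In 6M-8W the folds of Amh (-0.41), Gdf9 (-0.22), Bmp15 (-0.14) and Zp3 (-0.18) were below 0 without passing, as were 18 of 25 oocyte genes. In 6M-8W 10 of 12 luteal genes had folds above 0 (median 0.41; 0 past the threshold in edgeR and 0 adjusted over the list alone; adjusted p = 0.707 with an estimated correlation). The age difference of the luteal list at 8 weeks had a median of 1.33, with 5 genes past the threshold adjusted over the list alone (adjusted p = 0.129 with an estimated correlation).

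Most matrix genes fell in the same comparison. Of 20 matrix genes 14 fell and 1 rose (median -0.37; 17 down and 1 up adjusted over the list alone; adjusted p = 0.119 with an estimated correlation). Col1a1, a fibrillar collagen, fell by 0.63 ± 0.11 (adjusted p = 0.000281, lower in 16 of 16). Of the macrophage genes 7 of 16 fell (median -0.29; adjusted p = 0.409 with an estimated correlation). Fkbp5, which rose in the pituitary, fell in the ovary by 0.87 ± 0.15 (adjusted p = 0.000176, 13 of 16). The glucocorticoid list went both ways there, with 2 of 24 up and 7 down, and was called by fry (adjusted p = 0.00815) and not by camera (adjusted p = 0.165). Among the genes with the smallest adjusted p was Atp12a, a proton-potassium pump (ENSMUSG00000022229, chromosome 14 at 56365068 to 56388551), which fell by 3.81 ± 0.32 (adjusted p = 4.57e-08, 16 of 16). Also lower were the neuropeptide PACAP gene Adcyap1 (-3.36 ± 0.47, adjusted p = 2.22e-05, 16 of 16) and the carboxylesterase Ces2a (-3.53 ± 0.65, 13 of 16). Higher were the serine protease inhibitor genes Serpina3c (1.85 ± 0.21, adjusted p = 2.80e-06, 16 of 16) and Serpina5 (1.38 ± 0.20), the zinc finger gene Zfp536 (1.62 ± 0.17, 16 of 16), Bpifb4 (1.47 ± 0.19) and Oca2 (1.38 ± 0.22). Cyp11b1 (-4.28 ± 0.68) and Hist2h2aa1 (-8.28 ± 2.28) are near 0 in some libraries and high in others, which makes their folds uncertain.

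**Figure D4:**
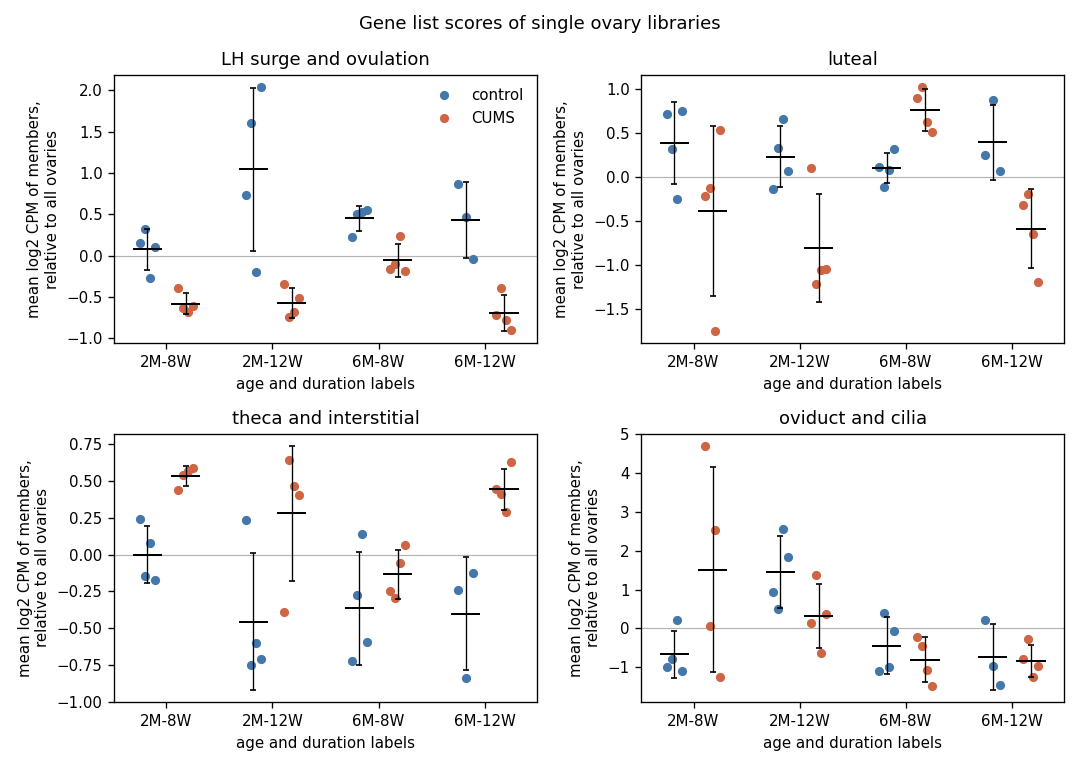
Score per ovary library (y axis, mean log2 CPM of the list's genes relative to all ovaries) for ovulation, luteal, theca, and oviduct and cilia genes, in control and stressed animals of each set (x axis), with bars for the mean ± SD. The ovulation score is above 0 in 12 of 15 control and 1 of 16 stressed ovaries.

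In 2M-8W ovaries the LH receptor and 3 other luteal genes fell. Lhcgr (ENSMUSG00000024107, chromosome 17 at 88741549 to 88791976) fell from 570 ± 151 to 187.5 ± 54.9 CPM (-1.60 ± 0.38, adjusted p = 0.0195, 4 of 4). Cyp11a1 fell from 7168 ± 1034 to 4006 ± 1560 (-0.84 ± 0.23, adjusted p = 0.0316) and Prlr by 0.89 ± 0.27 (adjusted p = 0.0472). With Fdxr (-0.57) they make 4 of 12 luteal genes that fell (6 adjusted over the list alone; median -0.61; adjusted p = 0.281 with an estimated correlation). Atp12a fell from 11.9 ± 2.21 to 0.92 ± 0.52 CPM (-3.62 ± 0.63, adjusted p = 0.00606, 4 of 4), and the protease inhibitor Timp1 by 2.16 ± 0.40 (adjusted p = 0.00939). Early response genes Fosl2 and Ier2 (both -0.84), the antioxidant enzyme Hmox1 (-0.95 ± 0.19) and Fkbp5 (664 to 332 CPM, adjusted p = 0.0400) fell too. Of the cell cycle genes 10 of 24 rose, Mki67 by 0.63 ± 0.14 (20 adjusted over the list alone; median 0.37; adjusted p = 0.281 with an estimated correlation). Of 18 clock genes 12 had folds of the same sign as in the pituitary, among them Arntl, down by 0.80 ± 0.15 (adjusted p = 0.0110). Hlf was up by 0.92 ± 0.21. The clock list was not called with an estimated correlation. All 20 interferon-response genes had folds below 0 (median -0.85; 0 passed in edgeR, and 0 adjusted over the list alone; adjusted p = 0.482 with an estimated correlation).

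Among the highest folds of this set are genes of motile cilia and of the oviduct, and they come from 2 of the 4 stressed ovaries. Hydin (6.22 ± 1.23, adjusted p = 0.0147), the axonemal dynein genes Dnah5 (5.98 ± 1.38) and Dnah3 (5.72 ± 1.47), Sec14l3 (6.28 ± 1.31), Cdhr3 (6.26 ± 1.58), BC048546 (6.30 ± 1.63), the ciliogenesis regulator Foxj1 (4.97 ± 1.13) and Pax8 (4.80 ± 1.16) rose. In all, 8 of 10 oviduct and cilia genes passed (10 adjusted over the list alone; median 4.73; adjusted p = 0.291 with an estimated correlation). So did 6 of 8 surface epithelium genes such as Krt18 (1.31) and Upk3b (1.02) (adjusted p = 0.281 with an estimated correlation). The oviduct and cilia score was 4.70 in stressed ovary 1 and 2.55 in ovary 3, against 0.05 and -1.25 in ovaries 2 and 4 and -1.10 to 0.23 in controls. The progesterone receptor Pgr (2.10 ± 0.50, adjusted p = 0.0196) goes with them, at 29.8 CPM in stressed ovary 1, and its fold without ovaries 1 and 3 is 0.41. Without those ovaries the count of 1113 is 0 in edgeR (1798 genes at an unadjusted p under 0.05; 1690 with DESeq2 and all libraries), and without control 4 it is 36. Lhcgr passed in 8 of 15 alternatives and Atp12a in 14.

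In 2M-12W ovaries 9 of 18 ovulation genes fell. Ptgs2, the prostaglandin synthase of the ovulating follicle (ENSMUSG00000032487, chromosome 1 at 150100031 to 150108227), went from 12.5 ± 14.7 to 0.46 ± 0.18 CPM (-4.73 ± 0.80, adjusted p = 0.00131), and the endothelin Edn2 from 25.2 ± 23.4 to 0.70 ± 0.40 (-5.19 ± 1.01, adjusted p = 0.00322). The EGF-like factor Ereg fell by 3.76 ± 0.65 (adjusted p = 0.00143) and the cumulus matrix gene Tnfaip6 by 2.96 ± 0.46 (adjusted p = 0.00103). The list had 9 of 18 past the threshold (13 adjusted over the list alone; median -1.87; adjusted p = 0.234 with an estimated correlation). Immediate early genes went with them, 10 of 20, for example Arc (-3.54 ± 0.61) and Egr3 (-2.56 ± 0.57) (14 adjusted over the list alone; median -0.87; adjusted p = 0.244 with an estimated correlation). So did 8 of 20 matrix genes, for example Col1a1 from 494 ± 210 to 262 ± 23.2 CPM (-0.92 ± 0.22, adjusted p = 0.0130) (12 down and 1 up adjusted over the list alone; adjusted p = 0.244 with an estimated correlation). The theca hormone Insl3 (1.53 ± 0.42, adjusted p = 0.0254) and Aldh1a1 (0.89 ± 0.20), 2 of 7 theca genes, rose (adjusted p = 0.244 with an estimated correlation), as did Esr2 (0.81 ± 0.24, adjusted p = 0.0422). Serpina3c rose from 15.3 ± 9.64 to 96.05 ± 35.2 CPM (2.64 ± 0.42, adjusted p = 0.00103, 4 of 4), with Oca2 (2.50 ± 0.44) and the glycoprotein hormone subunit Gpha2 (2.25 ± 0.48). Atp12a (-5.64 ± 0.71, adjusted p = 0.000137), Akr1b7 (-4.58 ± 0.81), Wnt10a (-4.15 ± 0.85) and Fkbp5 (-1.20 ± 0.29, adjusted p = 0.0136) fell. Controls differed widely among themselves in ovulation score (1.05 ± 0.99, against -0.57 ± 0.18 in stressed ovaries). The interferon gene Ifit3 (2.57 ± 0.69) has a fold of 0.84 without stressed ovary 1. In a fit of these groups alone 0 genes passed in edgeR (3465 at an unadjusted p under 0.05; 1745 with DESeq2 in the fit of all groups), and without control 2 the count was 332.

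In 6M-8W ovaries 9 of 20 interferon genes and 4 of 12 heat shock genes rose. Ifit3 went from 6.88 ± 1.13 to 69.5 ± 78.2 CPM (3.33 ± 0.70, adjusted p = 0.0314, 4 of 4) and Ifit1 from 7.12 ± 1.46 to 57.1 ± 58.8 (adjusted p = 0.0350, 4 of 4). Usp18 (2.62 ± 0.57), Isg15 (2.60 ± 0.64) and Oas2 (2.41 ± 0.53) rose with them, 9 of 20 interferon-response genes in all (20 adjusted over the list alone; median 1.86; adjusted p = 0.292 with an estimated correlation). The chaperone genes Hspa1a (1.19 ± 0.28), Hspa1b (1.45 ± 0.36), Hsp90aa1 (0.88 ± 0.22) and Hspd1 (0.42) rose, 4 of 12 (7 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). So did 3 of 20 genes of the unfolded protein response (adjusted p = 0.620 with an estimated correlation) and the plasma protein A2m (3.91 ± 0.92). Clock genes gave the firmest calls: Per3 (1.02 ± 0.16, adjusted p = 0.00359) and Nr1d2 (0.77 ± 0.12, adjusted p = 0.00359), each in all 14 alternatives. With Per2 (1.24 ± 0.24) and Tef (0.60 ± 0.13), 5 of 18 rose in all, a list call that held with an estimated correlation (adjusted p = 0.00192). Lower were the leukocyte receptor Cd244 (-3.37 ± 0.68), Wnt10a (-3.13 ± 0.76), Atp12a (-2.53 ± 0.59) and the matrix genes Col5a1 (-0.52) and Lox (-1.14), 2 of 20 (9 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). None of the 21 core genes passed. Col1a1 came closest (661 ± 83.9 to 366 ± 50.7 CPM, -0.85 ± 0.22, adjusted p = 0.0513, 4 of 4). The count of 199 fell to 4 without control 1, 6 without stressed ovary 4, 12 without control 4, 21 without stressed ovary 3 and 33 without control 2, and became 336 without control 3.

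In 6M-12W ovaries 12 of 20 immediate early genes fell, and some oocyte and granulosa genes rose. Fosl2 (-1.06 ± 0.18, adjusted p = 0.00175), Junb (-1.68 ± 0.37) and Btg2 (-1.28 ± 0.28) are among those that fell (16 adjusted over the list alone; median -1.19; adjusted p = 0.411 with an estimated correlation). Lower too were Timp1 (-2.02 ± 0.41), Runx2 (-3.10 ± 0.75) and Edn2 (-3.35 ± 0.95), among 5 of 18 ovulation genes (7 adjusted over the list alone; adjusted p = 0.411 with an estimated correlation). The egg coat genes Zp1 (1.05 ± 0.25, adjusted p = 0.00951) and Zp3 (29.6 ± 16.3 to 55.7 ± 6.83 CPM, 0.91 ± 0.26, adjusted p = 0.0237) and the oocyte factor Gdf9 (0.85 ± 0.26, adjusted p = 0.0315) rose, 7 of 25 oocyte genes in all (14 adjusted over the list alone; median 0.71; adjusted p = 0.411 with an estimated correlation). So did the granulosa genes Inha (2337 ± 162 to 4150 ± 446 CPM, 0.83 ± 0.25, adjusted p = 0.0295), Foxl2 (0.47) and the AMH receptor Amhr2 (0.71 ± 0.14), 3 of 17 (adjusted p = 0.546 with an estimated correlation). Prlr fell from 720 ± 217 to 287 ± 25.1 CPM (-1.33 ± 0.29, adjusted p = 0.00512) and Fkbp5 from 778 ± 273 to 313 ± 17.6 (-1.31 ± 0.31, adjusted p = 0.00822), each in 4 of 4. The guidance factor Sema3d fell under all 13 alternatives (241.5 ± 114 to 17.0 ± 11.3 CPM, -3.83 ± 0.76, adjusted p = 0.00309). Tnfrsf9 (-4.17 ± 1.04), Ces2a (-5.41 ± 1.34) and the acute-phase gene Saa2 (-5.14 ± 1.30) also fell. DNA replication genes Mcm2 (0.68 ± 0.11, adjusted p = 0.00111), Mcm3 (0.55) and Mcm5 (0.73) rose, 5 of 24 cell cycle genes (8 adjusted over the list alone; adjusted p = 0.546 with an estimated correlation). Higher too were the complement gene C7 (1.82 ± 0.42), Serpina3c (1.87 ± 0.45, adjusted p = 0.00980), Zfp536 (2.06 ± 0.38, adjusted p = 0.00227) and the water channel Aqp5 (1.75 ± 0.54). Cyp17a1 was at 166 ± 78.5 and 780.5 ± 88.4 CPM, higher in 4 of 4, without passing (2.23 ± 0.80, adjusted p = 0.0667). The count of 2032 fell to 550 without control 2, 844 without control 1, 1150 without stressed ovary 4 and 1291 without stressed ovary 1.

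Of the called genes, 10 fell in the ovary in all 4 sets, among them Atp12a, Wnt10a, the collagen gene Col5a1, the transglutaminase F13a1 and the calcium channel Cacna1c. 0 ovary genes rose in all 4. In the pituitary 10 genes rose in all 4 sets (Nr1d2, Tef, Glul, Per3, Bhlhe41, Rasd2, Ciart, Mettl7a1, Per2 and Dbp) and 4 fell (Npas2, Leo1, Aplnr and Arntl). The ovary sets of 12 weeks shared most by number: 2M-12W and 6M-12W had 155 genes up and 291 down in common, against 23.8 and 46.2 if calls were independent, and 3 in opposite directions. Relative to independent calls their up overlap was the highest (6.52 times), but not their down overlap (6.30 times). The latter was 11.7 times in 2M-8W with 6M-8W, 8.51 in 2M-8W with 2M-12W and 7.70 in 2M-12W with 6M-8W. The 6-month ovary sets shared least, with 3 up and 14 down in common (5.13 and 6.26 if independent) and 20 in opposite directions (11.4 if independent), and 40.8% of the genes called in either had the same sign.

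The question of the title, whether the response differs with age, was tested as a difference of stress effects. In the ovary 0 genes passed at 8 weeks in edgeR (2752 at an unadjusted p under 0.05; 534 with DESeq2) and 0 at 12 weeks (2043; 86 with DESeq2). With single libraries left out these counts reached 372 at 8 weeks and 4 at 12 weeks. The smallest p values at 8 weeks were those of Sdr42e1 (-1.12 ± 0.21) and Ttl (-0.51 ± 0.10), each with an adjusted p of 0.0811, and at 12 weeks those of Ankrd54 (0.57 ± 0.10) and the replication gene Mcm2 (0.75 ± 0.15), each at 0.0997. The interferon list had a median difference of 2.73 at 8 weeks, where 20 of 20 genes passed adjusted over the list alone (adjusted p = 0.129 with an estimated correlation), and of -1.35 at 12 weeks, where 0 did (adjusted p = 0.791 with an estimated correlation). In the pituitary at 8 weeks 31 genes passed: the stress effect was larger in 6-month animals for Fkbp5 (0.92 ± 0.19, adjusted p = 0.0338), Doc2b (1.84 ± 0.30, adjusted p = 0.00427), Nwd2 (2.28 ± 0.48), Tuba8 (1.47 ± 0.28) and the inositol transporter Slc2a13 (1.37 ± 0.25). It was lower for Hrh3 (-1.83 ± 0.39), Atp2a1 (-1.23 ± 0.24) and Rcor2 (-1.19 ± 0.23). The glucocorticoid list differed as a whole (median 0.39; 1 gene past the threshold and 8 adjusted over the list alone; adjusted p = 0.0279 with an estimated correlation). At 12 weeks 4 pituitary genes passed. Nr1d1 (ENSMUSG00000020889, chromosome 11 at 98767932 to 98775333) rose with stress in 2M-12W and was at 196 CPM in controls and 178 in stressed animals of 6M-12W (difference -2.30 ± 0.19, adjusted p = 1.67e-08). Dbp (-1.58 ± 0.29, adjusted p = 0.0356) and Tex11 (-2.17 ± 0.37, adjusted p = 0.0188; chosen after its values were seen) followed. For Nr1d1 and Dbp the sets differed mainly in controls, with 41.7 and 19.9 CPM in 2M-12W against 196 and 58.9 in 6M-12W, while stressed animals were at 187 and 119.5 against 178 and 118. The count of 31 ranged from 9 without 6M-8W stressed pituitary 3 to 104 without 6M-8W stressed pituitary 1. Doc2b passed in all 21 alternatives and Fkbp5 in 10. If control and stressed pituitaries of 6M-8W were sequenced apart, that batch is part of the 8-week differences and cannot be told apart from age. Levels of Hsd3b1, given below, differed between those arms.

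At 6 months the stress effects of the 12-week and the 8-week set differed. Duration cannot be told apart from other differences between these sets, whose controls differ too. In the 6-month ovary 1552 genes differed between 12 and 8 weeks of stress: Prlr (-1.81 ± 0.39, adjusted p = 0.00970), the cholesterol transporter Star (-2.62 ± 0.84, adjusted p = 0.0480) and Fkbp5 (-1.36 ± 0.42, adjusted p = 0.0435) had lower effects at 12 weeks. Higher effects had Amh (1.21 ± 0.38, adjusted p = 0.0442), Zp3 (1.10 ± 0.35, adjusted p = 0.0498) and Wnt6 (1.86 ± 0.45, adjusted p = 0.0142). Interferon genes differed downward, 6 of 20 (19 adjusted over the list alone; median -2.10), and cell cycle genes upward, 7 of 24 (13 adjusted over the list alone; median 0.47), each with an adjusted p = 0.525 with an estimated correlation. The immune receptor Tnfrsf9 (-6.31 ± 1.36, adjusted p = 0.00943) and Saa2 (-5.70 ± 1.61) had lower effects, and Myh6 (3.10 ± 0.94) and the fatty acid carrier Fabp3 (1.64 ± 0.52) higher ones. In the 6-month pituitary 61 genes differed, with lower effects at 12 weeks for Chrna6 (-2.99 ± 0.63), Nwd2 (-2.42 ± 0.47), Doc2b (-2.18 ± 0.30, adjusted p = 0.000533) and the glucocorticoid list (2 of 24 down, 8 adjusted over the list alone; adjusted p = 0.0123 with an estimated correlation). Effects were higher for Atp2a1 (1.92 ± 0.25, adjusted p = 0.000342). In 2-month ovaries 89 genes differed, 3 of them in the oviduct and cilia list. Cilia genes high in stressed ovaries 1 and 3 of 2M-8W had lower effects at 12 weeks (Hydin -7.95 ± 1.57, Foxj1 -6.71 ± 1.49). Aox1, an aldehyde oxidase gene, had a higher effect (0.91 ± 0.19) at 12 weeks, and without those ovaries 0 genes passed in edgeR (1301 at an unadjusted p under 0.05; 390 with DESeq2 and all libraries). In 2-month pituitaries 0 genes passed in edgeR (710 at an unadjusted p under 0.05; 3 with DESeq2), with Nr1d1 (0.97 ± 0.19, adjusted p = 0.177) the closest. The 1552 became 561 without 6M-12W control ovary 2 and 654 without control 1. With single libraries left out the 61 ranged from 27 to 122 and the 89 from 0 to 478.

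The design text of the series names only the younger animals with 8 weeks and the older ones with 12. For that pair of sets the difference of stress effects passed for 0 ovary genes in edgeR (3282 at an unadjusted p under 0.05; 501 with DESeq2), where Rhbdf2 (0.67 ± 0.12) and Ube2l3 (-2.25 ± 0.41) came closest with an adjusted p of 0.0551. With single libraries left out this count reached 972. In the pituitary 3 genes passed, Ahdc1 (-1.86 ± 0.32, adjusted p = 0.0200), Nr1d1 (-1.33 ± 0.19, adjusted p = 0.00169) and the predicted gene Gm29216 (adjusted p = 0.0426; chosen after its values were seen). Age and duration differ together in this comparison.

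In unstressed ovaries 51 genes differed between 6-month and 2-month mice, 2 of them in the macrophage list. Cd5l, a secreted macrophage protein, was higher by 1.93 ± 0.21 (adjusted p = 1.17e-05) and Gpnmb, a glycoprotein of lipid-laden macrophages, by 1.22 ± 0.21 (adjusted p = 0.00848), each in all 21 alternatives. 2 of 16 macrophage genes rose (9 adjusted over the list alone; median 0.50; adjusted p = 0.268 with an estimated correlation). Gdf3 (1.51 ± 0.27) and Csprs (1.41 ± 0.24) were also higher, and the matrix protein Dpt (-1.27 ± 0.28), Inmt (-2.27 ± 0.49) and Fmo2 (-0.91 ± 0.18) lower. Of the 51 genes 39 were higher and 12 lower. In control pituitaries 2740 genes differed (1216 higher at 6 months, 1524 lower). Gh (-0.51 ± 0.10, adjusted p = 0.00196), Tshb (-0.52 ± 0.12), Pomc (-0.53 ± 0.17), Lhb (-0.38 ± 0.12) and Cga (-0.36 ± 0.10) were lower and Gnrhr (0.31 ± 0.11) higher. From the 8W sets alone none of these 6 passed, and Lhb (0.14) and Gnrhr (-0.03) had the opposite direction. Elastin, Eln, was lower by 0.98 ± 0.13 (adjusted p = 8.75e-05). In all, 52 of 72 nuclear genes of oxidative phosphorylation and 52 of 80 ribosomal protein genes were lower (adjusted p = 0.509 and 0.569 with an estimated correlation). These counts go with the 6M-12W controls, whose mitochondrial share was 4.19 to 10.02% against 2.81 to 3.41% in the other controls. Without controls 3 and 4 of that set 19 and 16 genes were lower, and from the 8W sets alone 3 of the 72 were higher (median 0.08) and 6 of the 80 lower and 3 higher. The mitochondrial gene mt-Nd6 was higher by 1.46 ± 0.24 (adjusted p = 0.000661), and by 1.82 from the 8W sets alone (adjusted p = 0.0160). Its list of 13 mitochondrial genes did not hold there. The list median was 0.46 with 12 folds above 0, and from the 8W sets alone -0.03 with 5 above and 8 below 0. From the 8W sets alone the pituitary count is 116 and from the 12W sets alone 5532. Without the 6M-12W control pituitaries 3 and 4 it is 450, and without control 3 it is 1580. In the ovary it is 476 from the 8W and 1028 from the 12W sets alone, 24 without 6M-12W control 2, 31 without 2M-8W control 4, 83 without 2M-8W control 2 and 102 without 6M-12W control 3.

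Transcripts of the other tissue were present at low levels in most libraries. Prl, Gh and Cga, made in the pituitary, were found in ovary libraries at up to 0.0596% of their mean pituitary level in all groups but 2M-12W controls, where ovary 1 reached 0.740 to 1.01%, and at 0.00207% or less in 3 of the 4 control ovaries of 2M-8W. The steroid enzyme Hsd3b1 was at 3.25 ± 0.92 CPM in 2M-8W control pituitaries and 4.66 ± 0.98 in stressed ones, at 2.12 and 4.23 in 2M-12W (2 of 4 stressed above all controls), at 0 in 6M-8W controls and 3.68 ± 0.31 in stressed ones, and at 0 in all 6M-12W pituitaries. Mean Cyp11a1 was higher in stressed than control pituitaries in all 4 sets. Prl was at 25.9 ± 2.02 CPM in control and 68.0 ± 12.2 in stressed ovaries of 6M-12W, but at 46.8 ± 6.51 and 51.4 ± 11.5 in 6M-8W. If control and stressed samples of a set were sequenced apart, that batch and stress cannot be told apart in it. The calls of Cga (-3.47) and Prl (-3.18) in 2M-12W ovary, of Hsd3b1 and Cyp11a1 (3.13) in 6M-8W pituitary, of Cyp11a1 (1.78) in the pituitary mean of the 4 sets, of Hsd3b1 in the age difference at 8 weeks and of Hsd3b1 and Cyp11a1 (-4.49) in pituitary controls of different age go with these levels. Without control ovary 1 the 2M-12W ovary folds are -1.09 for Cga and -0.74 for Prl.

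**Figure D5:**
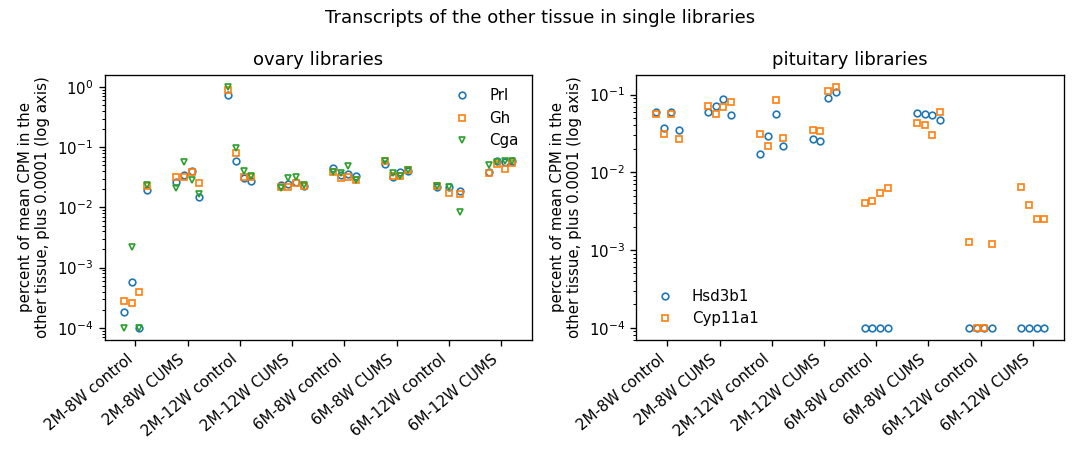
Level of Prl, Gh and Cga in ovary libraries and of Hsd3b1 and Cyp11a1 in pituitary libraries, as a percentage of the gene's mean CPM in the other tissue plus 0.0001 (y axis, log scale), per library of each group (x axis). Hsd3b1 is at 0 in 6M-8W control and all 6M-12W pituitaries.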

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

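The 7 tests weighed in the next 3 paragraphs were chosen after the results were seen, and the splits of the samples were set before.

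In the mean of the 4 sets most ovulation and early response genes and part of the luteal genes were lower in stressed ovaries. The granulosa, oocyte and theca lists were not lower with them: the lowest of those 3 list medians was 0.33 (log2), which argues against tissue from outside the ovary as the cause in that mean. No list kept its call there with an estimated correlation. In 6M-8W the argument does not hold, since most oocyte genes had folds below 0 and most luteal genes above 0. Tissue from outside the ovary is not absent, with oviduct and cilia scores of 4.70 and 2.55 in 2M-8W stressed ovaries 1 and 3 and a fat score of 2.71 in 2M-12W stressed ovary 2, though 2M-12W controls reached 2.55 and 2.52 as well. For a lower share of luteal tissue alone, the ovulation and luteal medians were compared. The ovulation genes as a group had a median of -1.34, below the luteal median of -0.35. Both medians were known when this test was chosen. Medians of different gene lists also do not measure the share of a tissue, so the test cannot decide on that explanation. The ovulation score varied 3.1 times as much among controls (SD 0.57) as among stressed ovaries (SD 0.18), mostly through the 2M-12W controls (SD 0.99), and in 6M-8W the SD was 0.15 in controls and 0.20 in stressed ovaries; 12 of 15 controls but 1 of 16 stressed ovaries lay above 0. A candidate explanation, open for want of the estrous stage and not borne out by the spread in 6M-8W, is that fewer stressed ovaries were taken near ovulation.

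Clock genes differed between stressed and control animals in both tissues, and the folds of ovary and pituitary correlated with Pearson's r of 0.773 in the mean of the 4 sets. Another hour of collection in the stressed arm may be the explanation, since it predicts such a shared change. Glucocorticoid action in its place predicts a larger clock difference in 6M-8W pituitaries, where the glucocorticoid genes rose most, only if that difference grows with the glucocorticoid response. The difference there, less the mean of the 2-month sets, was -0.50 ± 0.23 (log2). This cannot decide against glucocorticoid action, since such growth was not tested. Controls of 6M-12W were also apart from other controls (2.38 against 0.52 to 0.79 in pituitary), so the measure moved without stress too. A stress effect on the clock itself stays open and was not tested.

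Pituitary hormone transcripts in ovary libraries may be reads carried over between libraries. Of 31 ovary libraries 28 hold them, with each of Prl, Gh and Cga at 0.005% or more of its pituitary level. In 27 of the 28 the highest of these percentages lay within 2 times the lowest (median ratio of highest to lowest 1.22, highest 2.24). For the steroid enzymes in pituitary libraries, carry-over and steroid enzyme expression in the stressed pituitary cannot be told apart by the test run: mean Hsd3b1 was higher in stressed than control pituitaries in 3 of the 4 sets and at 0 in both arms of 6M-12W. Controls of 2-month animals held it as well (mean 2.69 CPM, SD 1.16). As shares of the ovary level, mean Hsd3b1 and Cyp11a1 were 0.0477 and 0.0424% in 2M-8W controls and 0.0683 and 0.0692% in stressed animals. In 6M-8W they were 0 and 0.00489% in controls and 0.0539 and 0.0429% in stressed animals. Both enzymes moving together, in controls too, goes with carry-over, but their common ratio was not tested and their levels are low.

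Other splits of the same libraries show where chance is unlikely. The real split counts among them, so 1 of 35 or 1 of 100 is the lowest possible share, which cannot exclude chance. In the ovary, 3 of 35 splits gave as many genes as the real 1113 in 2M-8W (highest other 1224), so chance is not shown to be unlikely there. 1 of 35, the real split, did so in 2M-12W (1197, highest other 861), 6M-8W (199, highest other 3) and 6M-12W (2032, highest other 2). In the mean of the 4 sets 1 of 100 did so (3615, highest other 1). Chance is thus unlikely for these, though the shares were not adjusted over the comparisons. For age in controls 3 of 100 gave as many (real 51, highest other 685), so chance is unlikely but not excluded. For differences of stress effects the splits cannot decide, because they shuffle control and stressed libraries within sets. They stand for no stress effect at all, not for equal effects across sets. For duration at 6 months 1 of 100 gave as many (real 1552, highest other 1), and at 2 months 4 of 100 (real 89, highest other 1841). Splits with many times the real count point to a structure of the samples. For counts of 0 the splits decide nothing, because any split gives at least 0 and so 100 of 100 gave as many: the age difference at 8 weeks (highest other 105), at 12 weeks (highest other 1498, again a structure of the samples) and the 6M-12W minus 2M-8W effect (highest other 60). Those counts of 0 are from edgeR (2752, 2043 and 3282 genes at an unadjusted p under 0.05; 534, 86 and 501 with DESeq2).

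In the pituitary chance is unlikely, again without adjustment over the comparisons, in 2M-8W (1 of 35 splits, real 72, highest other 1), 2M-12W (1 of 35, real 99, highest other 2), 6M-8W (1 of 35, real 799, highest other 63) and the mean of the 4 sets (1 of 100, real 1095, highest other 138). Chance is not shown to be unlikely in 6M-12W, where 3 of 35 gave as many as 47. The highest other was 251, several times the real count, which points to a structure of the samples. For age in controls 1 of 100 gave as many, with another split close to it (real 2740, highest other 2726), so chance is unlikely there. For the differences of stress effects the splits cannot decide, for the reason given for the ovary. The shares were 3 of 100 for the age difference at 8 weeks (real 31, highest other 193) and 3 of 100 at 12 weeks (real 4, highest other 4). They were 4 of 100 for duration at 6 months (real 61, highest other 175) and 4 of 100 for the 6M-12W minus 2M-8W effect (real 3, highest other 12). Several of these differences again have splits with several times the real count. Duration at 2 months had 0 genes in edgeR (710 at an unadjusted p under 0.05; 3 with DESeq2); 100 of 100 splits gave as many, which a count of 0 fixes in advance (highest other 2).

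Stress effects that differed between ages or durations by a test of the difference are listed here as log2 differences. Between 12 and 8 weeks in 2-month ovaries these were Aox1 0.91, Armcx6 0.83, Chkb 0.68, Scpep1 0.52, Hydin -7.95, Ttc21a -7.48, Dnah5 -7.44, Sec14l3 -7.08 and Foxj1 -6.71. Without 2M-8W stressed ovaries 1 and 3, where cilia genes were high, 0 genes passed for this difference in edgeR. In that fit 1301 were at an unadjusted p under 0.05, and DESeq2 with all libraries gave 390. In 6-month ovaries they were Myh6 3.10, Aldh1l2 1.91, Wnt6 1.86, Afmid 1.72, Fabp3 1.64, Ugt1a1 -11.36, Tnfrsf9 -6.31, Ssu2 -6.27, Ces2a -6.06, Saa2 -5.70, Star -2.62, Amh 1.21, Prlr -1.81, Zp3 1.10 and Fkbp5 -1.36. In 6-month pituitaries they were Pcdhga2 5.24 (uncertain for its shared exons), Atp2a1 1.92, Pla2g2c 1.62, Rcor2 1.02, Chrna6 -2.99, Ncapg2 -2.46, Nwd2 -2.42, Doc2b -2.18 and Slc26a1 -2.11. Between ages in the pituitary at 8 weeks they were Hsd3b1 8.50 (a fitted value against a group at 0, and no bound), Nwd2 2.28, Doc2b 1.84, Tuba8 1.47, Slc2a13 1.37, Hrh3 -1.83, Pla2g2c -1.26, Atp2a1 -1.23, Rcor2 -1.19, F2rl1 -0.86 and Fkbp5 0.92, and at 12 weeks Nr1d1 -2.30 and Dbp -1.58. For 6M-12W minus 2M-8W in the pituitary they were Ahdc1 -1.86 and Nr1d1 -1.33.

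Single libraries lay far from the other 3 of their group, by the gap to the nearest divided by the range, in 33 of 409 groups tested (8.07%). Chance gives about 1 in 20. In the ovary these were, for 2M-12W stressed ovary 1, Lhcgr (0.899, at 396.5 CPM against 203 to 223), Fkbp5 (0.880) and the luteal (0.876) and glucocorticoid (0.864) scores. For 2M-12W control 1, Cyp17a1 (0.923) and the theca score (0.847). For 2M-12W stressed ovary 2 the fat score (0.842). For 2M-8W stressed ovary 1, Pgr (0.886) and the clock score (0.845). For 6M-8W control 3, the mitochondrial share (0.894) and Pgr (0.882). For 6M-8W control 1 the ovulation score (0.853). For 6M-8W stressed ovary 1, Pgr (0.959), and stressed ovary 2, Fshr (0.880). For 6M-12W stressed ovary 2, Cyp17a1 (0.888).

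In the pituitary the same measure singled out, for 2M-12W control 1, Lhb (0.839), Gnrhr (0.970), Crhr1 (0.905) and Fkbp5 (0.853). For 2M-12W control 3, Avpr1b (0.878). For 2M-12W stressed pituitary 1 the interferon score (0.858) and for stressed pituitary 3 the corticotrope score (0.892). For 2M-8W control 1, Fkbp5 (0.856), and control 4, the total count (0.837). For 6M-8W control 4, Cga (0.957). For 6M-8W stressed pituitary 1, the mitochondrial share (0.911) and Inhbb (0.861). For 6M-12W control 2, Fshb (0.872, at 270 CPM against 51.4 to 79.5). For 6M-12W stressed pituitary 1, the total count (0.964), Crhr1 (0.903) and Tsc22d3 (0.879). For 6M-12W stressed pituitary 2, Inhbb (0.915) and Egr1 (0.924).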

How the results depend on the processing

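The alternatives without the 2M-8W stressed ovaries 1 and 3, without the 6M-12W control pituitaries 3 and 4, without genes of the other tissue, and with the 8W or the 12W sets alone were chosen after seeing the data. The mean of the 4 sets, 3615 genes in ovary and 1095 in pituitary, stayed within 1.5 times under each alternative run. Of 466 named gene results in ovary 403 kept direction and side of the threshold with DESeq2, 63 newly passed and 0 reversed. Without a filter 422 did so and 44 no longer passed. In a fit of own groups only 279 of 436 did so and 139 of the 225 called no longer passed, and with the replicate block 312 of 456 and 140 of 240. With each library left out in turn 881 of 2627 called results no longer passed and 3 reversed. Of 312 in pituitary 281 did so with DESeq2 and 308 without a filter, 239 of 290 in own groups only (46 of 108 called no longer passed) and 264 of 295 with the replicate block (23 of 109). The cause was not tested for any of the changes below, except that leaving out libraries leaves fewer samples. With 12536371 counts in the smallest library, genes under a mean log2 CPM of 1 were not named for their fold, though core genes and list members were.

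With DESeq2 the ovary counts were 1690 (2M-8W), 603 (6M-8W), 534 and 86 (age difference at 8 and 12 weeks), 390 and 2332 (duration at 2 and 6 months), 501 (6M-12W minus 2M-8W) and 157 (age in controls). In pituitary 109 (2M-8W), 230 (2M-12W), 128 (6M-12W), 118 and 15 (age difference), 3 and 182 (duration) and 8 (6M-12W minus 2M-8W). Genes shared between sets, up and down, were with DESeq2 in ovary 93 and 256 (2M-8W, 2M-12W), 23 and 84 (2M-8W, 6M-8W), 88 and 230 (2M-8W, 6M-12W), 41 and 97 (2M-12W, 6M-8W), 251 and 472 (2M-12W, 6M-12W) and 18 and 35 (6M-8W, 6M-12W). In pituitary 12 down (2M-8W, 2M-12W), 21 down (2M-8W, 6M-12W), 49 and 27 (2M-12W, 6M-8W), 15 down (2M-12W, 6M-12W) and 19 up (6M-8W, 6M-12W). RLE size factors gave 3 ovary genes for 6M-12W minus 2M-8W. No filter on low counts gave 84 (ovary 6M-8W) and 45 (ovary duration at 2 months), and shared genes of 93 down (2M-8W, 2M-12W), 1 and 15 (2M-8W, 6M-8W), 16 and 79 (2M-8W, 6M-12W), 7 and 17 (2M-12W, 6M-8W), 1 and 9 (6M-8W, 6M-12W) in ovary and 4 down (2M-12W, 6M-12W) in pituitary.

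A fit of own groups only gave in ovary 2 (2M-8W), 0 (2M-12W; edgeR, 3465 at an unadjusted p under 0.05; 1745 with DESeq2 on all groups), 99 (6M-8W), 1 and 2 (age difference at 8 and 12 weeks), 0 (duration at 2 months; 1634 unadjusted; 390 with DESeq2), 2637 (duration at 6 months) and 29 (age in controls), and in pituitary 18 (2M-8W), 7 (6M-12W), 17 and 1 (age difference), 33 (duration at 6 months), 1 (6M-12W minus 2M-8W) and 1214 (age in controls). With the replicate number as a block the ovary counts were 125, 784, 28 and 662 in the 4 sets in order of age and duration, 0 (duration at 2 months; edgeR, 1882 unadjusted; 390 with DESeq2 without the block) and 766 (duration at 6 months), and the pituitary age difference at 12 weeks 1. The correlation of control and stressed libraries of 1 number was -0.24 to 0.20 in ovary and -0.07 to 0.27 in pituitary. The own number was the best match in 4 of 15 in ovary and 6 of 16 in pituitary. These values do not settle whether the numbers pair controls with stressed animals. Between ovary and pituitary the own number was the best match in 20 of 31, more often than a random pick among the 4 pituitaries of a group would give. The correlations were low, with a median of 0.03 against -0.01 for other numbers. This goes with shared animals but does not settle it. No test uses this.

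Without the 2M-8W stressed ovaries 1 and 3 the counts were 0 (2M-8W; edgeR, 1798 unadjusted; 1690 with DESeq2 and all libraries), 0 (duration at 2 months; 1301 unadjusted; 390 with DESeq2) and 2 (6M-12W minus 2M-8W), and Cdhr3 (-0.98), Esr1 (-0.10) and Fam107a (-0.10) reversed. Without the 6M-12W control pituitaries 3 and 4 they were 40 (6M-12W, 16 of them among the 47), 9 (age difference at 12 weeks), 6 (6M-12W minus 2M-8W) and 450 (age in controls), and Lhb (-0.27), Pgr (0.79) and Pmvk (-0.019) reversed in 6M-12W. Age in controls gave 476 in ovary and 116 in pituitary from the 8W sets only, where Lhb (0.14) and Gnrhr (-0.03) reversed, and 1028 and 5532 from the 12W sets only.

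With an estimated inter-gene correlation the list calls went in ovary from 21, 18, 14 and 16 in the 4 sets to 0, 0, 1 and 0, from 15 to 0 in their mean, from 18 and 10 to 0 and 0 for the age difference, from 11 and 17 to 0 and 0 for duration, from 9 to 0 for 6M-12W minus 2M-8W and from 10 to 0 for age in controls. In pituitary they went from 13, 9, 5 and 14 to 0, 0, 1 and 1, from 11 to 4 in the mean, from 6 and 8 to 1 and 0, from 4 and 9 to 0 and 1, from 6 to 0 and from 3 to 0 in the same order.

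With each library left out in turn the ovary counts ranged from 36 to 1673 (2M-8W), 332 to 1724 (2M-12W), 4 to 336 (6M-8W), 550 to 2266 (6M-12W), 2748 to 3997 (mean), 0 to 372 and 0 to 4 (age difference), 0 to 478 and 561 to 1856 (duration), 0 to 972 (6M-12W minus 2M-8W) and 24 to 102 (age in controls). Counts that moved by over 1.5 times were, in 2M-8W, 45 and 36 without controls 2 and 4 and 114, 1673 and 397 without stressed 1, 2 and 3. In 2M-12W, 332 and 598 without controls 2 and 4 and 697, 393 and 776 without stressed 2, 3 and 4. In 6M-8W, 4, 33, 336 and 12 without controls 1 to 4 and 21 and 6 without stressed 3 and 4. In 6M-12W, 844 and 550 without controls 1 and 2 and 1291 and 1150 without stressed 1 and 4. For duration at 2 months they were 167, 160, 5 and 4 without 2M-12W controls 1 to 4, 2, 136, 0 and 5 without its stressed 1 to 4, 3, 3, 0 and 7 without 2M-8W controls 1 to 4 and 0, 478, 0 and 449 without its stressed 1 to 4. For duration at 6 months they were 903, 868 and 796 without 6M-8W controls 1 and 2 and stressed 3, and 654, 561, 1006, 953 and 1021 without 6M-12W controls 1 and 2 and stressed 1, 3 and 4. For age in controls they were 83 and 31 without 2M-8W controls 2 and 4 and 24 and 102 without 6M-12W controls 2 and 3. From 0, the age difference at 8 weeks became 140 and 87 without 6M-8W control 3 and stressed 1, and 1, 1 and 372 without 2M-8W control 1 and stressed 1 and 4. At 12 weeks 4 and 1 without 2M-12W controls 1 and 3 and 1 without 6M-12W stressed 4. 6M-12W minus 2M-8W became 7, 4, 972, 2 and 200 without 2M-8W control 2 and stressed 1 to 4, and 1 and 28 without 6M-12W controls 1 and 3. Reversed were Cyp19a1 in 2M-8W (range -0.81 to 0.27, the highest without control 3) and, in 6M-12W without control 2, Hsd3b1 (range -0.15 to 0.22) and Nr3c1 (range -0.28 to 0.15).

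In pituitary the ranges were 41 to 76 (2M-8W), 34 to 178 (2M-12W), 436 to 991 (6M-8W), 22 to 92 (6M-12W), 918 to 1253 (mean), 9 to 104 and 1 to 5 (age difference), 0 to 1 and 27 to 122 (duration), 1 to 4 (6M-12W minus 2M-8W) and 1580 to 3935 (age in controls). Counts that moved by over 1.5 times were, in 2M-8W, 45 and 41 without control 4 and stressed 2. In 2M-12W, 178, 35, 41 and 48 without controls 1 to 4 and 56, 42 and 34 without stressed 1 to 3. In 6M-8W, 511, 455 and 436 without control 4 and stressed 3 and 4. In 6M-12W, 92, 31 and 22 without controls 1 and 3 and stressed 4. For the age difference at 8 weeks they were 15, 19, 17, 104, 9 and 12 without 6M-8W controls 1, 2 and 4 and stressed 1, 3 and 4, and 17, 47 and 17 without 2M-8W control 3 and stressed 2 and 4. At 12 weeks 1, 1, 2, 1, 2 and 2 without 2M-12W controls 2 to 4 and stressed 2 to 4, and 2, 1, 2 and 2 without 6M-12W control 1 and stressed 1, 3 and 4. For duration at 6 months they were 37, 108, 27 and 30 without 6M-8W control 3 and stressed 1, 3 and 4, and 117, 122, 38 and 29 without 6M-12W controls 1, 2 and 4 and stressed 4. At 2 months 1 without 2M-8W control 1. For 6M-12W minus 2M-8W 1 gene was left without each of 2M-8W control 2, stressed 1 and 2, and 6M-12W control 1 and stressed 3, and for age in controls 1580 without 6M-12W control 3. Reversed in 6M-8W were Dmbt1 (range -7.49 to 1.87, the highest without control 3) and Avpr1b (range -0.053 to 0.29, the lowest without stressed 2). In 2M-8W without control 1 these were Pax7 (range -0.017 to 0.41, the lowest there) and Hsph1 (range -0.69 to 0.041, the highest there). In 6M-12W they were Gnrhr (range -0.081 to 0.21, the lowest without control 1), Fshb (range -0.78 to 0.52, the highest without control 2), Lhb (range -0.12 to 0.23, the lowest without control 3) and Pgr (range -0.30 to 0.37, the highest without control 3). Adjusted p of the reversed results named in this part lay between 0.316 and 0.984.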
